A study of Nitrosopumilus maritimus SCM1 with 7 samples.

How the data were processed

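Total RNA of N. maritimus SCM1 cultures at 5, 50 or 750 nM copper was treated to remove DNA, depleted of ribosomal RNA and made into stranded libraries, per the labels' protocols. The deposited files hold whole-number counts of reads per gene for 7 libraries, with no normalization. The submitters' processing notes name FastQC, Trimmomatic, STAR, HTSeq and DESeq2. Their versions, the genome build, the annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical copies, may not be told apart. The total of each file lies below the read number that the labels state per sample.

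Each file had 1795 gene entries and 5 entries that name no gene. The latter stayed out of library sizes and tests. Reads outside any gene made up 34.7% and 39.3% of all entries in replete replicates 1 and 3, and reads that were not unique made up 32.7% and 23.0%. Gene counts made up 24.7% of all entries in limited replicate 1 and 39.2% in limited replicate 3. No column was left unmatched to a sample. The libraries were grouped by the copper supply in their labels. Pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom from 14.3 to 158, so none was counted as a duplicate.

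Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and plots used Python 3.11.15 with matplotlib 3.10.9. The following choices were made before the data were examined. All 7 libraries entered a single edgeR quasi-likelihood fit with group as the only term, TMM scaling and filterByExpr, which kept 1777 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The standard error was derived from the F statistic and the log2 change. Lists with at least 3 measured members, 7 in number, were tested with camera at a preset correlation of 0.01 and adjusted over the lists. An estimated correlation, fry and camera on limma-voom values served as alternatives. CPM values were scaled by the gene counts of each library. Log2 levels for ranges used a prior count of 2.

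The lists were ammonia monooxygenase, ammonium transporters, multicopper oxidases and nitrite reductase, complex I, complexes III and IV, the 3-hydroxypropionate/4-hydroxybutyrate cycle, cell division, hydroxyectoine synthesis, phosphate and phosphonate, and cell surface. Of 29 lists fixed, these 10 were given by locus tags. The other 19 were defined by product names only and were not analysed here, because no annotation was used. The cell surface list held Nmar_1547 alone, and 1 of the 2 tags of the phosphate and phosphonate list was measured. The rule for named genes had 3 parts per comparison. It took the genes with the largest log2 change in each direction among those called, with a mean over the 7 libraries of at least 20 CPM after TMM scaling and no overlap between the groups, then the members of the ammonia monooxygenase, ammonium transporter and multicopper oxidase lists, and then up to 3 members with the smallest p of every other list with a passing camera test or at least 3 called members. The rule set 6 genes per direction for its opening part, and 2 are named because the files pair no tag with a product. Nmar_0585, Nmar_0011, Nmar_1708 and Nmar_1766 are named outside the rule, chosen after their values were seen.

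Depth sets the precision. The 95% intervals of shares are exact binomial (Clopper-Pearson) and cover counting error only, as do the floors of 3 counts, since no molecular identifiers mark single molecules. The floor was 88.5 CPM in limited replicate 1, 10.2 in limited replicate 3, 2.90 in toxic replicate 1, 2.12 in toxic replicate 2, 4.35 in toxic replicate 3, 1.02 in replete replicate 1 and 1.04 in replete replicate 3. In limited replicate 1, 338 genes had 0 counts, against 102 and 83 in the replete libraries.

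The tests were checked on simulated counts for 1777 genes drawn from the real means and library sizes, with 200 genes changed by known folds. For limited against replete, edgeR recovered 20.0% of genes changed 2-fold, 83.3% of those changed 4-fold and 98.0% of those changed 8-fold, and 5.84% of its calls were false. For toxic against replete it recovered 28.9%, 97.9% and 100% at those folds, with 1.88% false. These shares were measured on the 1648 simulated genes that passed the filter. Apart from the changed genes, every simulated library had the same mean profile. The false shares therefore leave out profile differences between libraries and are not error rates of the reported calls.

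Alternatives fixed beforehand were DESeq2, limma-voom, RLE, upper quartile or library totals in place of TMM, no filter or at least 50 counts in every library of a group, a fit of only the groups compared, the replicate number as a block, robust dispersion, an adjusted p under 0.01 and each library left out in turn. Where that left a group with 1 library, it was assumed to vary like the libraries of the other groups. Alternatives chosen after the data were seen were thinning every library to 33897 counts, leaving out Nmar_1547 before totals, leaving out both limited replicate 3 and toxic replicate 1, expression-matched random lists (50 nearest genes per member) and a mixture model. The mixture model sets the expected count of a gene to a share of the replete profile plus a share of an even background profile. That profile was what remained of limited replicate 3, or of toxic replicate 1, after removing the replete profile scaled on 20 abundant anchor genes. The library used as source was then left out of the test. In simulated counts for 1730 genes with different background shares and no changed gene, edgeR made 1025 calls for limited and 1054 for toxic against replete without the mixture term, and 0 and 1 with it. With 200 genes of higher replete level raised 4-fold in the toxic libraries the mixture test recovered 30.5% and made 1 false call. Both simulations used a set dispersion of 0.05, not one estimated from these libraries, and changed no gene in the limited libraries.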

Results

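Nitrosopumilus maritimus SCM1 is a marine archaeon that lives by oxidizing ammonia to nitrite, a pathway with several copper-dependent enzymes. Its transcriptome was measured by RNA sequencing after acclimation to 3 copper supplies, in medium freed of trace metals and buffered with 1 µM TETA, a metal chelator. The groups were copper-replete (50 nM, 2 libraries, replicates 1 and 3), copper-limited (5 nM, 2 libraries, replicates 1 and 3) and copper-toxic (750 nM, 3 libraries). Counts assigned to genes totalled 2931570 and 2882055 in replete replicates 1 and 3, and 33897 and 293353 in limited replicates 1 and 3. They totalled 1032813, 1412605 and 689444 in toxic replicates 1, 2 and 3. A floor of 3 counts corresponded to 88.5 CPM (gene counts scaled to the same total in every library) in limited replicate 1 and to 1.02 CPM in replete replicate 1. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The files hold 1795 locus tags and do not pair them with names. The gene names given here belong to lists fixed beforehand. They were written down from memory of the strain's published annotation and were not checked against it, so what each named tag and list stands for needs checking.

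The gene for the S-layer protein, Nmar_1547, which forms the cell envelope, dominated the replete libraries with 81.8% ± 0.024 of gene counts (SD, n = 2). It held 39.7% ± 40.4 in the limited group (n = 2) and 44.8% ± 16.2 in the toxic group (n = 3). Single libraries held 68.2% in limited replicate 1 (exact 95% interval 67.7% to 68.7%) and 11.1% in limited replicate 3 (11.0% to 11.2%). In toxic replicates 1, 2 and 3 the share was 27.5%, 47.1% and 59.7%. The Nmar_1547 differences under TMM scaling were log2 -4.27 for limited against replete (edgeR adjusted p = 0.634) and log2 -3.84 for toxic against replete (edgeR adjusted p = 0.629). DESeq2 called both, with log2 -4.19 (DESeq2 adjusted p = 0.00659) and -3.90 (DESeq2 adjusted p = 0.00839), and edgeR against library totals called both, with log2 -1.04 (edgeR adjusted p = 0.00486) and -0.87 (edgeR adjusted p = 0.00914). Counts were also spread over different numbers of genes. Replete libraries reached 90% of their gene counts with 7 and 8 genes, limited replicates 1 and 3 with 336 and 1086, and toxic replicates 1, 2 and 3 with 961, 608 and 196. Outside Nmar_1547 the numbers were 241 and 266 in replete replicates 1 and 3, 831 and 1125 in limited replicates 1 and 3, and 1093, 925 and 599 in toxic replicates 1, 2 and 3. The limited pair had a Spearman correlation across genes of 0.782, below the 0.913 between limited replicate 3 and toxic replicate 1, whereas the replete pair stood at 0.956. Limited replicate 1 had a median of 3 counts per gene, against 106 in limited replicate 3 and 252 in toxic replicate 1. Counting noise may therefore lower the value of the limited pair. Genes are not independent replicates, and these correlations only describe the libraries.

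**Figure D1:**
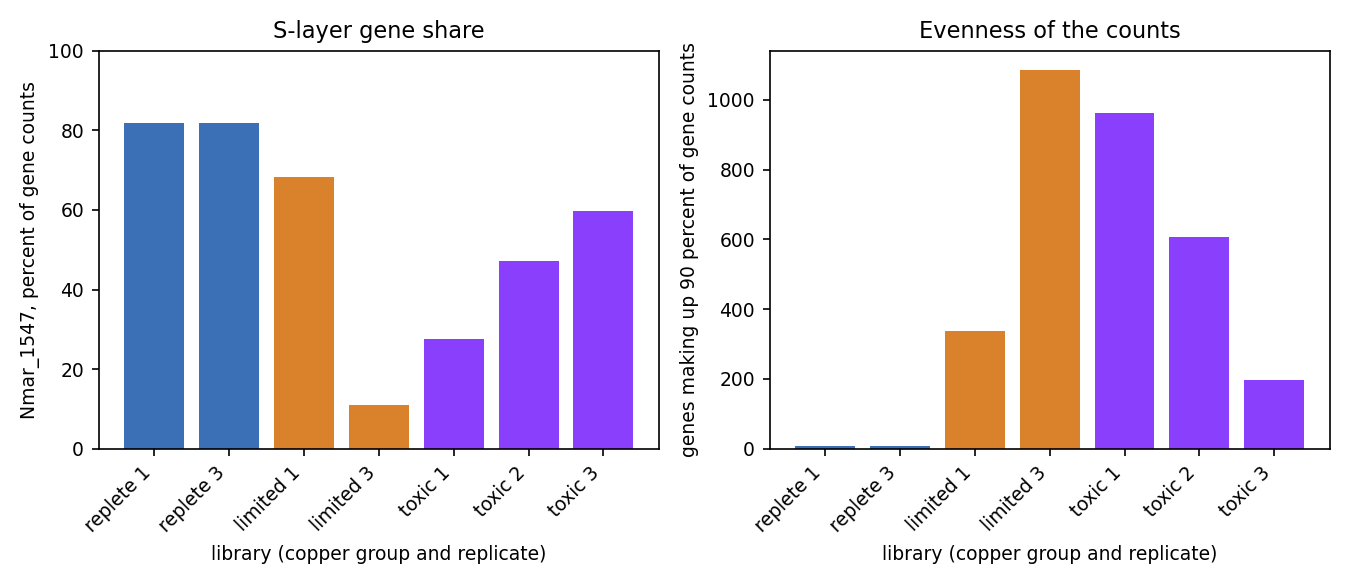
Left, bars give the share of gene counts (percent) held by the S-layer gene Nmar_1547 in each of the 7 libraries. Right, bars give the number of genes that together make up 90 percent of gene counts, from 7 in replete replicate 1 to 1086 in limited replicate 3.

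The scaling decided the sign of many differences from replete libraries. Against library totals alone the median gene shifted by log2 4.66 in limited against replete, by 3.89 in toxic against replete and by -0.78 in toxic against limited. With Nmar_1547 left out before totals were taken, a setting chosen after the data were seen, the shifts were 2.84, 2.20 and -0.64. Changes are therefore given relative to the median gene (TMM scaling), with the value against library totals beside them wherever the direction turns. A mixture of the replete profile and an even background, also chosen after the data were seen, was set as the expected level in another alternative. Genes at 0 counts in both replete libraries have no expected replete level and could not enter it, among them the named Nmar_0135, Nmar_0625 and Nmar_0087. The source library was left out, so with limited replicate 3 as source the limited group was limited replicate 1 alone. Few calls may therefore reflect low power. In simulated counts the mixture test recovered 30.5% of genes raised 4-fold in the toxic libraries, at a set dispersion of 0.05. Changes in the limited libraries were not simulated, so the power for limited against replete is not known. With limited replicate 3 or toxic replicate 1 as the background's source, edgeR then called 4 and 46 genes in limited against replete, 96 and 43 in toxic against replete and 17 and 200 in toxic against limited. Of these, 2 and 38, 9 and 6, and 10 and 112 were also called in the same direction without the mixture. Of 26 named genes, 0 and 3 were called in their reported direction in limited against replete, and 2 and 0 in toxic against replete, where 1 and 1 were called in the other direction. In toxic against limited 5 and 11 of 25 were called in their reported direction and 1 and 2 in the other.

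Copper limitation was compared with copper-replete growth to ask how the transcriptome changes when copper is scarce. Transcripts of several copper enzymes were lower relative to the median gene. Against library totals the listed genes Nmar_1259 and Nmar_1663 turned (log2 1.09 and 1.45), and Nmar_1354 was not called (log2 -0.33). The copper nitrite reductase gene nirK, Nmar_1667, held 13775 ± 565 CPM in replete (SD, n = 2) and 3657 ± 2505 CPM in limited libraries (n = 2) and fell by 5.31 on the log2 scale (SE 2.07, edgeR adjusted p = 0.0308). It was also lower against library totals, by log2 -1.92. A further multicopper oxidase gene, Nmar_1131, rose from 4.30 ± 0.191 to 466 ± 367 CPM. Its log2 change was 2.36 relative to the median gene (SE 0.44, edgeR adjusted p = 0.000135) and 6.77 against library totals. Against the mixture Nmar_1131 departed by log2 0.74 with limited replicate 3 as source and 0.45 with toxic replicate 1, without passing (edgeR adjusted p = 0.809 and 0.998). The listed genes of ammonia monooxygenase, the copper enzyme that starts ammonia oxidation, held means of 4216 to 21049 CPM in replete and 2078 to 14842 CPM in limited libraries.

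Of the 4 ammonia monooxygenase genes, 0 rose, 2 fell and 2 did not pass the test in limited against replete libraries, with 2 calls adjusted over the list alone. The genes that fell were amoX, Nmar_1501 (log2 -4.10, SE 1.49, edgeR adjusted p = 0.0212), and amoC, Nmar_1502 (log2 -4.41, SE 1.5, edgeR adjusted p = 0.0146). For amoA, Nmar_1500, the level was 21049 ± 2143 CPM in replete and 14842 ± 13263 CPM in limited libraries, with a log2 difference of -3.79 (SE 2.27, edgeR adjusted p = 0.150). Without limited replicate 3 the edgeR adjusted p was 0.213 for Nmar_1501 and 0.173 for Nmar_1502. Both calls were also lost without replete replicate 1 (edgeR adjusted p = 0.0828 and 0.0695) and without replete replicate 3 (edgeR adjusted p = 0.0746 and 0.0516), whereas amoB, Nmar_1503, passed without limited replicate 1, toxic replicate 1 or toxic replicate 3 (edgeR adjusted p = 0.0195, 0.0398 and 0.0351). DESeq2 called all 4 as lower, among them Nmar_1500 (log2 -3.71, DESeq2 adjusted p = 0.0108) and Nmar_1503 (log2 -3.60, DESeq2 adjusted p = 0.0365). Against library totals Nmar_1501 and Nmar_1502 differed by log2 -0.73 and -1.05 and were not called (edgeR adjusted p = 0.233 and 0.0991), nor were they with the replicate block (edgeR adjusted p = 0.136 and 0.0950), and the list's median was -0.62. The camera set test gave an adjusted p of 0.0169, with an adjusted p = 0.313 with an estimated correlation and a camera adjusted p = 0.181 on limma-voom values.

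Of the 2 ammonium transporter genes, Nmar_0588 fell by 4.02 on the log2 scale (SE 1.04, edgeR adjusted p = 0.00216) and Nmar_1698 differed by log2 -4.17 without passing (SE 2.17, edgeR adjusted p = 0.0974), with 1 call adjusted over the list alone. In CPM, Nmar_0588 held 1409 ± 107 in replete and 1256 ± 65.5 in limited libraries, and without limited replicate 3 its edgeR adjusted p was 0.0974. Against library totals it differed by log2 -0.16 and was not called (edgeR adjusted p = 0.821). Without limited replicate 1, Nmar_1698 passed (edgeR adjusted p = 0.0408), as it did in DESeq2 (log2 -4.09, DESeq2 adjusted p = 0.00454). Among the 6 multicopper oxidase and nitrite reductase genes, 1 rose, 4 fell and 1 did not pass, with 5 calls adjusted over the list alone. The second nirK gene, Nmar_1259, fell by 3.41 relative to the median gene (SE 0.65, edgeR adjusted p = 0.000182), whereas against library totals it differed by log2 1.09. Nmar_1663 fell by 3.07 (SE 0.59, edgeR adjusted p = 0.000194), against 1.45 under library totals. The calls of Nmar_1354 and Nmar_1667 were lost without limited replicate 3 (edgeR adjusted p = 0.136 and 0.200) and without replete replicate 1 (edgeR adjusted p = 0.0550 and 0.101). The Nmar_1667 call was also lost without replete replicate 3 (edgeR adjusted p = 0.0942) and without toxic replicate 2 (edgeR adjusted p = 0.0735). With the replicate block both were lost (edgeR adjusted p = 0.0877 and 0.228), and against library totals Nmar_1354 went from log2 -4.25 to -0.33 and was not called (edgeR adjusted p = 0.573). Nmar_1136 differed by log2 0.31 (edgeR adjusted p = 0.508) and passed against library totals (log2 4.75, edgeR adjusted p = 7.43e-05). The list's median was -3.24 relative to the median gene and 1.27 against library totals (camera adjusted p = 0.102, and adjusted p = 0.313 with an estimated correlation). The list passed in the fry set test (adjusted p = 0.0362) and in camera against library totals (adjusted p = 0.000935).

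Most listed genes of complex I, complexes III and IV and carbon fixation fell relative to the median gene under copper limitation. Their list calls were lost with an estimated correlation (camera adjusted p = 0.313 for each), and their medians turned positive against library totals. All 10 tested of the 11 listed complex I genes fell, with 10 calls adjusted over the list alone and a median of -1.96, against 2.53 under library totals. Nmar_0279 fell by 2.01 relative to the median gene (SE 0.47, edgeR adjusted p = 0.00104) and differed by 2.49 against library totals. All 7 genes of respiratory complexes III and IV fell, with 7 calls adjusted over the list alone and a median of -2.88, against 1.49 under library totals. Of 14 genes of the 3-hydroxypropionate/4-hydroxybutyrate cycle, which fixes carbon dioxide, 2 rose, 9 fell and 3 did not pass, with 11 calls adjusted over the list alone and a median of -1.62, against 2.79 under library totals. Nmar_1308 fell by 5.17 on the log2 scale (SE 0.99, edgeR adjusted p = 0.000194), from 876 ± 18.1 to 447 ± 216 CPM, and was not called against library totals (log2 -0.93, edgeR adjusted p = 0.210). Camera adjusted p-values were 0.00155 for complex I, 0.00155 for complexes III and IV and 0.00395 for the carbon fixation cycle at the preset correlation. Limited replicate 3 stood apart from limited replicate 1, with 1086 against 336 genes in 90% of its counts, and without it edgeR called as lower 1 gene of complex I, 0 of complexes III and IV and 4 of the carbon fixation cycle. DESeq2 called as lower 8 genes of complex I, 7 of complexes III and IV and 8 of the carbon fixation cycle. Without limited replicate 3 the edgeR adjusted p was 0.0717 for Nmar_0277 of complex I and 0.0716 for Nmar_0183 of complexes III and IV.

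All 6 cell division genes fell relative to the median gene under limitation, with 6 calls adjusted over the list alone and a median of -2.45, against 2.01 under library totals (camera adjusted p = 0.00252, and adjusted p = 0.313 with an estimated correlation). The CdvB paralog gene Nmar_0061, whose family acts in archaeal cell scission, fell by 5.30 on the log2 scale (SE 1.10, edgeR adjusted p = 0.000364), from 1683 ± 327 to 775 ± 428 CPM, and was not called against library totals (log2 -1.09, edgeR adjusted p = 0.144). CdvC, Nmar_1088, fell by 2.66 (SE 0.54, edgeR adjusted p = 0.000315), against 1.82 under library totals, and its edgeR adjusted p was 0.0781 without limited replicate 3, where 1 of the 6 genes was called. Of 4 genes for hydroxyectoine synthesis, which makes an osmolyte, 2 rose, 0 fell and 2 did not pass, with 2 calls adjusted over the list alone (median 1.48, camera adjusted p = 0.177, and adjusted p = 0.499 with an estimated correlation). Without limited replicate 3, replete replicate 1 or replete replicate 3, 1 of these rose, and DESeq2 called 1 as higher. DESeq2 called 5 of the cell division genes as lower. The measured gene of the phosphate and phosphonate list, Nmar_0155, differed by log2 -0.57 relative to the median gene and by 3.9 against library totals, and did not pass (edgeR adjusted p = 0.246). Against 10000 random lists matched on mean expression, a comparison chosen after the data were seen, the medians lay at percentile 1.36 for complex I, 3.98 for complexes III and IV, 15.2 for cell division, 21.8 for the carbon fixation cycle and 51.6 for ammonia monooxygenase.

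Across 1777 tested genes, edgeR called 1057 in limited against replete libraries, 555 that rose and 502 that fell relative to the median gene, and 548 and 499 of these by at least 2-fold. The split followed abundance: among the 889 genes of lower mean level 403 rose and 107 fell, and among the 888 of higher mean level 152 rose and 395 fell. By the naming rule, Nmar_0135 and Nmar_0625 had 0 counts in both replete libraries and were at least 338-fold and at least 210.1-fold higher in limited libraries in CPM, against a floor of 3 counts over the replete group. These bounds were set on library totals, where the median gene shifted by log2 4.66. After TMM scaling the limited libraries held 48.5 ± 6.61 and 52.9 ± 49.2 CPM of Nmar_0135 and Nmar_0625. Without replete replicates 1 and 3 in turn, the floor was higher and the bounds were 168-fold and 170.4-fold for Nmar_0135 and 104-fold and 106-fold for Nmar_0625. The Nmar_0135 bound was 562-fold without limited replicate 1, which held 2 counts of it, under that library's floor, so no bound is given without limited replicate 3. Nmar_0788 fell by 6.61 on the log2 scale (SE 0.83, edgeR adjusted p = 9.09e-06), from 334 ± 101 to 71.0 ± 58.7 CPM. Against library totals it differed by log2 -2.03 and was not called (edgeR adjusted p = 0.0673), and limited replicate 1 held 1 count of it, or 29.5 CPM, under that library's floor of 88.5 CPM. Nmar_0221, also called as lower by edgeR, held 1 count in the limited group against 62 in the replete group. Its CPM ratio, pooled over each group's libraries, was 0.287, with an exact 95% interval of 0.00714 to 1.66 that covers counting error only. Its call was lost without limited replicate 3 (edgeR adjusted p = 0.276) and against library totals (log2 -1.83, edgeR adjusted p = 0.397). Upper quartile scaling raised the share of calls that rose from 52.5% to 67.1%, and against library totals 1472 of 1479 called genes rose. The number of calls was 158 without limited replicate 3 and 384 with neither that library nor toxic replicate 1, a pair left out after the data were seen.

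**Figure D2:**
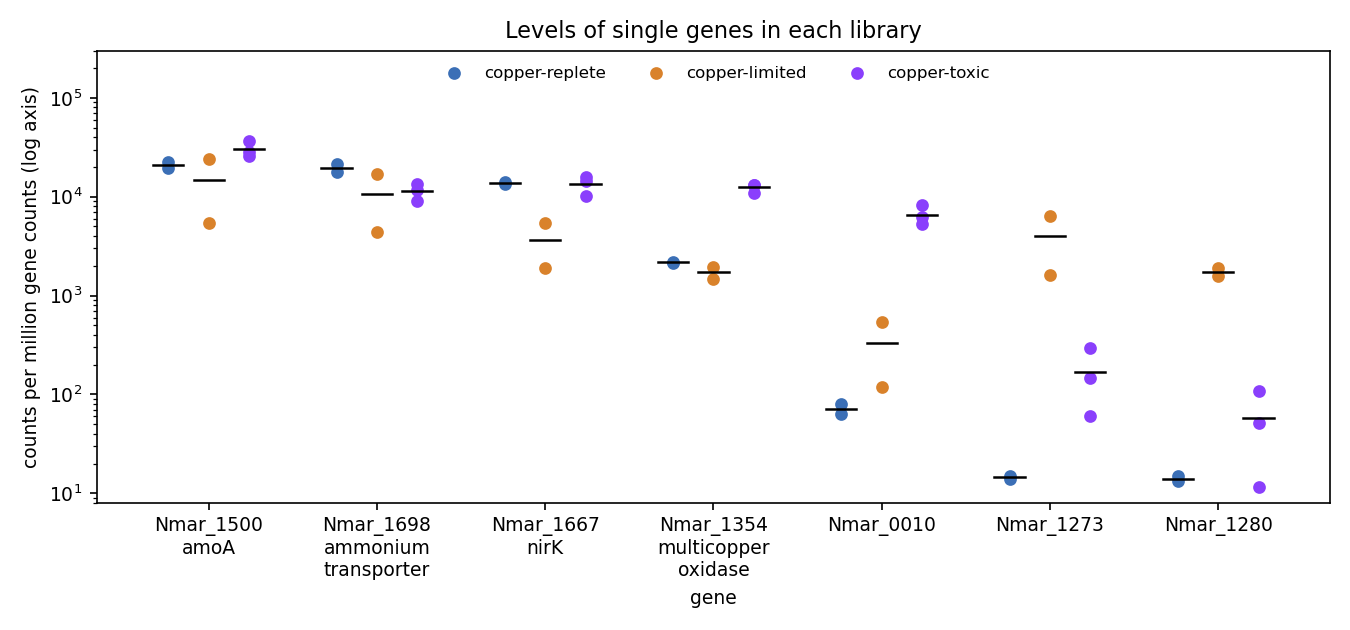
Points give the level of 7 genes in each library in CPM, on a log axis, coloured by copper group, and black lines give group means. Nmar_1273 and Nmar_1280 lie at 14.4 and 14.1 in replete and at 4005 and 1731 in limited libraries, and Nmar_0010 lies at 6606 in toxic libraries.

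Copper toxicity was compared with copper-replete growth to ask how the transcriptome changes under excess copper. The multicopper oxidase gene Nmar_1131 rose from 4.30 ± 0.191 CPM in replete (SD, n = 2) to 197 ± 151 CPM in toxic libraries (n = 3). Its log2 change was 1.77 relative to the median gene (SE 0.39, edgeR adjusted p = 0.000902) and 5.49 against library totals. Toxic replicates 1, 2 and 3 held 359, 173 and 59.5 CPM of it, and against the mixture it departed by log2 -0.30 with limited replicate 3 as source and 0.041 with toxic replicate 1, without passing (edgeR adjusted p = 0.780 and 1.00). Another, Nmar_1354, held 2161 ± 54.0 CPM in replete and 12427 ± 1344 CPM in toxic libraries. Its direction depended on the scaling, with log2 -0.61 relative to the median gene (SE 1.03, edgeR adjusted p = 0.639) and 2.52 against library totals (edgeR adjusted p = 0.000166). All 10 tested genes of complex I and 6 of the 7 of complexes III and IV fell relative to the median gene, with list medians that turned positive against library totals and list calls that were lost with an estimated correlation (camera adjusted p = 0.331 and 0.419).

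Of the 4 ammonia monooxygenase genes 0 rose, 0 fell and 4 did not pass in toxic against replete libraries, and 0 passed when adjusted over the list alone. In edgeR 2 of the 4 had an unadjusted p under 0.05, and DESeq2 called 0. The level of amoA, Nmar_1500, was 21049 ± 2143 CPM in replete and 30288 ± 5371 CPM in toxic libraries, with log2 -2.55 relative to the median gene (SE 1.86, edgeR adjusted p = 0.252) and 0.53 against library totals. The list's median was -2.62 relative to the median gene and 0.42 against library totals (camera adjusted p = 0.0273, with adjusted p = 0.419 with an estimated correlation and 0.192 on limma-voom values, and a fry adjusted p = 0.111). Without toxic replicate 3, Nmar_1501, Nmar_1502 and Nmar_1503 passed (edgeR adjusted p = 0.00972, 0.00765 and 0.0342), and Nmar_1502 also passed without limited replicate 1 or 3 (edgeR adjusted p = 0.0358 and 0.0363) and with RLE scaling (edgeR adjusted p = 0.0440). Of the ammonium transporter genes, Nmar_0588 fell by 2.97 relative to the median gene (SE 0.83, edgeR adjusted p = 0.00578) and differed by 0.22 against library totals, and Nmar_1698 differed by log2 -3.84 without passing (SE 1.81, edgeR adjusted p = 0.0775). Both passed when adjusted over the list alone. The Nmar_0588 call was lost without replete replicate 1 (edgeR adjusted p = 0.0521) or toxic replicate 2 (edgeR adjusted p = 0.0549) and with the replicate block (edgeR adjusted p = 0.133), and Nmar_1698 passed without limited replicate 1 or 3 or toxic replicate 3 (edgeR adjusted p = 0.0440, 0.0443 and 0.050) and in DESeq2 (log2 -3.90, DESeq2 adjusted p = 0.00497). In CPM, Nmar_1698 held 19433 ± 2503 in replete and 11377 ± 2310 in toxic libraries.

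Among the 6 multicopper oxidase and nitrite reductase genes 1 rose, 2 fell and 3 did not pass in toxic against replete libraries, with 3 calls adjusted over the list alone. The genes that fell relative to the median gene, Nmar_1259 (log2 -1.71, edgeR adjusted p = 0.00748) and Nmar_1663 (log2 -1.24, edgeR adjusted p = 0.0270), differed by 1.59 and 2.07 against library totals. Without replete replicate 1 their edgeR adjusted p was 0.116 and 0.0983, and without toxic replicate 2 it was 0.0575 and 0.127. The Nmar_1663 call was also lost without replete replicate 3 (edgeR adjusted p = 0.147) and without toxic replicate 1 (edgeR adjusted p = 0.0635). With the replicate block both calls were lost (edgeR adjusted p = 0.0566 and 0.0803). The nirK gene Nmar_1667 held 13421 ± 2879 CPM in toxic libraries, with log2 -3.10 relative to the median gene (SE 1.6, edgeR adjusted p = 0.104) and -0.037 against library totals. DESeq2 called it as lower (log2 -3.16, DESeq2 adjusted p = 0.0178). Nmar_1136 had a log2 difference of 0.045 (edgeR adjusted p = 0.922) that turned to -0.26 without replete replicate 3 and passed against library totals (log2 3.75, edgeR adjusted p = 0.000806). The list's median was -0.92 relative to the median gene and 2.29 against library totals (camera adjusted p = 0.241, and adjusted p = 0.423 with an estimated correlation).

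All 10 tested complex I genes fell relative to the median gene under toxicity, with 10 calls adjusted over the list alone and a median of -1.43, against 2.14 under library totals (camera adjusted p = 2.38e-05, and adjusted p = 0.331 with an estimated correlation). Nmar_0277 fell by 2.29 (SE 0.37, edgeR adjusted p = 9.23e-05), against 1.18 under library totals, with 90.5 ± 5.96 CPM in replete and 205 ± 78.0 CPM in toxic libraries. Of the 7 genes of complexes III and IV, 0 rose, 6 fell and 1 did not pass, with 7 calls adjusted over the list alone and a median of -1.67, against 1.66 under library totals. Nmar_0185 fell by 2.79 relative to the median gene (SE 0.68, edgeR adjusted p = 0.00206), against 0.44 under library totals. Without replete replicate 1 edgeR called 6 genes of complex I and 3 of complexes III and IV, and without toxic replicate 2 it called 6 of complex I. DESeq2 called 8 genes of complex I and 5 of complexes III and IV as lower.

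Of the 14 carbon fixation genes 1 rose, 7 fell and 6 did not pass in toxic against replete libraries, with 8 calls adjusted over the list alone and a median of -1.06, against 2.53 under library totals. The genes that fell numbered 2 without replete replicate 1 or toxic replicate 2 and 4 without replete replicate 3 or toxic replicate 1, and the gene that rose, Nmar_0841, was not called without replete replicate 3 (edgeR adjusted p = 0.0529). Of the 6 cell division genes 0 rose, 5 fell and 1 did not pass, with 5 calls adjusted over the list alone and a median of -1.01, against 2.36 under library totals. They numbered 1 without replete replicate 1 or 3, 2 without toxic replicate 1, 3 without limited replicate 3 and 0 without toxic replicate 2, and DESeq2 called 2. Nmar_0700 (log2 -2.89, against 0.26 under library totals) had an edgeR adjusted p of 0.0601, 0.0785 and 0.0871 without replete replicates 1 and 3 and toxic replicate 2. For Nmar_0029 (log2 -1.04, against 2.33 under library totals) the edgeR adjusted p was 0.132, 0.0977, 0.0713 and 0.165 without replete replicates 1 and 3 and toxic replicates 1 and 2, and the DESeq2 adjusted p was 0.0719. With the replicate block both were lost (edgeR adjusted p = 0.175 and 0.110). Camera adjusted p-values were 0.00152 for complexes III and IV, 0.0197 for carbon fixation and 0.0144 for cell division, each with an adjusted p = 0.419 with an estimated correlation. Cell division did not pass in fry (adjusted p = 0.0543) and carbon fixation did not pass in camera against library totals (adjusted p = 0.114). Against the expression-matched random lists the medians lay at percentile 0.26 for complex I, 4.16 for complexes III and IV, 8.54 for carbon fixation, 12.7 for ammonia monooxygenase and 42.7 for cell division. Of the 4 hydroxyectoine genes 2 rose, 0 fell and 2 did not pass, with 2 calls adjusted over the list alone (median 1.29, camera adjusted p = 0.141, and adjusted p = 0.439 with an estimated correlation), and 1 rose in DESeq2 and without replete replicate 1 or 3 or toxic replicate 1 or 2. Nmar_0155 of the phosphate and phosphonate list did not pass, with log2 -0.42 relative to the median gene and 3.30 against library totals (edgeR adjusted p = 0.294). Toxic replicate 1, which reached 90% of its counts with 961 genes, held 284 CPM of the complex I gene Nmar_0277, against 128 CPM in toxic replicate 3, which reached it with 196.

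In toxic against replete libraries edgeR called 923 genes, 549 that rose and 374 that fell relative to the median gene, and 526 and 329 of these by at least 2-fold. Among the 889 genes of lower mean level 411 rose and 75 fell, and among the 888 of higher mean level 138 rose and 299 fell. Nmar_0087 and Nmar_0135, at 0 counts in replete libraries, were at least 176-fold and at least 110.0-fold higher in CPM in toxic libraries. Library totals set these bounds, and against them the median gene shifted by log2 3.89. After TMM scaling the toxic libraries held 37.2 ± 16.4 and 25.1 ± 6.19 CPM of Nmar_0087 and Nmar_0135. Without toxic replicate 1, which held the most of both, these bounds were 80.7-fold and 55.3-fold, without replete replicate 1 they were 87.4-fold and 54.5-fold and without replete replicate 3 they were 88.9-fold and 55.5-fold. Nmar_1580 fell by 4.28 on the log2 scale (SE 0.48, edgeR adjusted p = 3.08e-06), from 65.9 ± 26.5 to 36.9 ± 4.38 CPM, and Nmar_1294 fell by 4.02 (SE 0.59, edgeR adjusted p = 3.28e-05), from 38.4 ± 17.5 to 24.5 ± 11.2 CPM. Against library totals both calls were lost, with log2 -0.84 and -0.65 (edgeR adjusted p = 0.504 and 0.603). Upper quartile scaling raised the share of calls that rose from 59.5% to 75.9%, and against library totals 1491 of 1492 called genes rose. The number of calls was 505 without replete replicate 1, 564 without replete replicate 3 and 576 without toxic replicate 2, and 743 with neither limited replicate 3 nor toxic replicate 1.

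**Figure D3:**
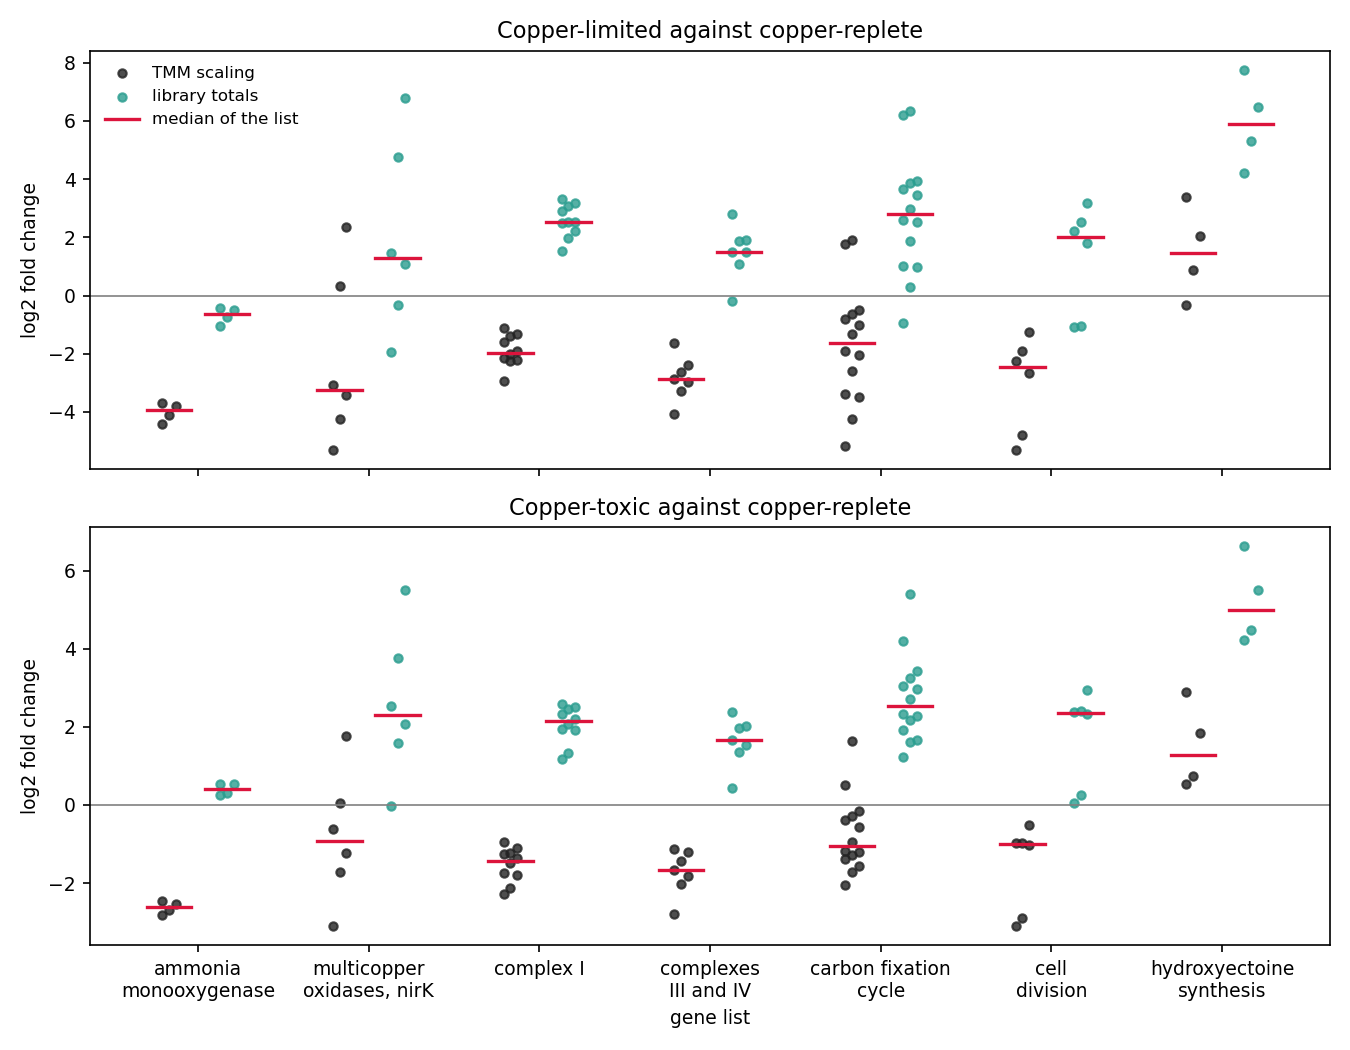
Points give the log2 fold change of each tested member of 7 gene lists, with red lines at list medians, for limited against replete (top) and toxic against replete libraries (bottom). Black points are relative to the median gene (TMM scaling) and green points against library totals, where the complex I medians turn from -1.96 to 2.53 under limitation and from -1.43 to 2.14 under toxicity.

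Toxic and limited libraries were compared to ask where excess and scarcity of copper differ. Nmar_1273 and Nmar_1280, whose products the files do not name, stood highest in the limited libraries. Nmar_1273 held 4005 ± 3389 CPM in limited (SD, n = 2), 169 ± 120 CPM in toxic (n = 3) and 14.4 ± 0.799 CPM in replete libraries (n = 2), and fell by 4.93 on the log2 scale from limited to toxic (SE 0.71, edgeR adjusted p = 0.000284). Nmar_1280 held 1731 ± 221, 57.6 ± 49.2 and 14.1 ± 1.29 CPM in the same groups and fell by 4.84 (SE 0.50, edgeR adjusted p = 1.39e-06). In the other direction Nmar_0010 rose from 330.0 ± 299.8 CPM in limited to 6606 ± 1501 CPM in toxic libraries, a log2 change of 5.57 (SE 0.97, edgeR adjusted p = 0.00201), against 4.22 under library totals. Without limited replicates 1 and 3 in turn its log2 change was 5.51 and 5.71, and its call was lost (edgeR adjusted p = 0.0568 and 0.355). Nmar_0221 was also called as higher, with 92 counts in the toxic and 1 in the limited group. Its CPM ratio, pooled over each group's libraries, was 9.60, with an exact 95% interval of 1.68 to 383 that covers counting error only. That call was lost without any of the replete or limited libraries (edgeR adjusted p = 0.0741, 0.0740, 0.118 and 0.779 without replete replicates 1 and 3 and limited replicates 1 and 3), and against library totals (log2 3.40, edgeR adjusted p = 0.834).

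Of the 6 multicopper oxidase and nitrite reductase genes 1 rose, 0 fell and 5 did not pass in toxic against limited libraries, with 3 calls adjusted over the list alone. The gene that rose was Nmar_1663, with log2 1.84 (SE 0.55, edgeR adjusted p = 0.0420), and leaving out any of 6 libraries ended that call, with edgeR adjusted p from 0.0506 without toxic replicate 3 to 0.484 without limited replicate 3. The call was also lost against library totals (log2 0.61, edgeR adjusted p = 0.834), where the list's median was 0.55. Nmar_1354 differed by log2 3.64 without passing (SE 1.24, edgeR adjusted p = 0.0736) and passed without toxic replicate 1 (edgeR adjusted p = 0.00951), with library totals (log2 2.85, edgeR adjusted p = 0.000345) and in DESeq2 (log2 3.53, DESeq2 adjusted p = 1.42e-06). Against the mixture it departed by log2 2.07 with limited replicate 3 as source and 3.42 with toxic replicate 1 (edgeR adjusted p = 0.00439 and 1.75e-07). DESeq2 called 3 of these 6 as higher, 5 of the 11 carbon fixation genes it tested, 2 of 6 cell division genes and 1 of the 6 genes of complexes III and IV it tested. Of the 14 carbon fixation genes 2 rose, 0 fell and 12 did not pass, with 7 calls adjusted over the list alone (median 0.57, against -0.38 under library totals). Nmar_1308 rose by log2 3.60 (SE 0.91, edgeR adjusted p = 0.0178) and Nmar_1110 by 2.18 (SE 0.59, edgeR adjusted p = 0.0261). Against library totals both calls were lost, with log2 2.58 and 0.95 (edgeR adjusted p = 0.0524 and 0.834). Without limited replicate 3 their edgeR adjusted p was 0.533 and 0.576, without limited replicate 1 it was 0.108 and 0.142, without replete replicate 1 it was 0.0668 and 0.0633 and without replete replicate 3 it was 0.0685 and 0.0704. Of the 6 cell division genes 1 rose, 0 fell and 5 did not pass, with 2 calls adjusted over the list alone and a median of 1.47, against 0.38 under library totals. The gene that rose, Nmar_1088 (log2 1.69, SE 0.51, edgeR adjusted p = 0.0438), was not called without replete replicates 1 and 3 (edgeR adjusted p = 0.0912 and 0.0928), limited replicates 1 and 3 (edgeR adjusted p = 0.162 and 0.595) or toxic replicates 2 and 3 (edgeR adjusted p = 0.0696 and 0.0583). Against library totals it was not called either (log2 0.57, edgeR adjusted p = 0.834). With the replicate block the calls of Nmar_1663, Nmar_1308 and Nmar_1088 were lost (edgeR adjusted p = 0.0779, 0.144 and 0.0665). Of the 7 genes of complexes III and IV edgeR called 0, with 2 at an unadjusted p under 0.05, 1 call adjusted over the list alone and a median of 1.19, against 0.12 under library totals. DESeq2 called Nmar_1544 of that list (log2 1.91, DESeq2 adjusted p = 0.0288). Camera adjusted p-values were 0.0234 for carbon fixation, 0.0145 for cell division and 0.0447 for complexes III and IV, each with an adjusted p = 0.558 with an estimated correlation, and in fry the adjusted p was 0.299, 0.299 and 0.333. Without toxic replicate 1 edgeR called as higher 3 of the multicopper oxidase and nitrite reductase genes, 6 of carbon fixation, 3 of cell division and 3 of complexes III and IV, with 1 carbon fixation gene lower. Without toxic replicate 3 it called 3 carbon fixation genes higher and 1 lower. Camera called these 3 lists, against 1 list without limited replicate 3 and 5 lists without toxic replicate 1 or toxic replicate 2. Complexes III and IV lost their call without replete replicates 1 and 3 (camera adjusted p = 0.0526 and 0.0556), limited replicate 3 (camera adjusted p = 0.660) and toxic replicate 3 (camera adjusted p = 0.166), carbon fixation without limited replicate 1 (camera adjusted p = 0.0797) and cell division without limited replicate 3 (camera adjusted p = 0.111).

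In toxic against limited libraries edgeR called 0 of the 4 ammonia monooxygenase genes, 0 of the 2 ammonium transporter genes, 0 of the 10 complex I genes and 0 of the 4 hydroxyectoine genes, with 0 calls for each when adjusted over the list alone. None of them had an unadjusted p under 0.05 in edgeR, and DESeq2, which tested 8 of the complex I and 1 of the hydroxyectoine genes, called 0. Medians were 1.42 for ammonia monooxygenase (camera adjusted p = 0.0843), 1.77 for the multicopper oxidases and nitrite reductase (camera adjusted p = 0.0823), 0.24 for complex I, against -0.59 under library totals (camera adjusted p = 0.419), and -0.19 for hydroxyectoine synthesis (camera adjusted p = 0.558). With an estimated correlation these were adjusted p = 0.558, 0.558, 0.685 and 0.753. Ammonia monooxygenase passed without limited replicate 1, toxic replicate 1 or toxic replicate 2 (camera adjusted p = 0.00109, 0.0216 and 0.0383) and against library totals (camera adjusted p = 3.37e-06), and turned without limited replicate 3. The multicopper oxidases and nitrite reductase passed without toxic replicate 1 or 2 (camera adjusted p = 0.0279 and 0.0429) and against library totals (camera adjusted p = 0.000293). Nmar_0155 differed by log2 0.15 relative to the median gene and -0.59 against library totals. Across all genes edgeR called 120, of which 110 rose and 10 fell, against 10 (8 rose and 2 fell) under library totals. The number of calls was 3 without limited replicate 3, 9 without limited replicate 1, 54 and 56 without replete replicates 1 and 3, 74 without toxic replicate 2 and 292 without toxic replicate 1. It was 31 with neither limited replicate 3 nor toxic replicate 1.

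The calls of both comparisons with replete libraries overlapped in 816 genes of the same direction, 492 that rose and 324 that fell, where independent lists would share 277 (171 and 106). Against library totals 1397 calls were shared, and 7 called genes fell in limited and 1 in toxic against replete. The number that fell in both therefore depends on the scaling. The correlation of log2 changes across 1777 genes was 0.926, against a mean of 0.567 in 100 simulations of unchanged groups tested against the same replete libraries. The covariance was 3.91, against 0.132 in the simulations, and 91.7% of genes had the same sign, against 68.6%. The simulations gave a mean of 0 genes called by edgeR in both comparisons. That was built in, as they held no changed gene and no background, so they only weigh the sharing of replete libraries. A background that separates the replete from the limited and toxic libraries could also give shared calls and was not simulated for the overlap. The replete libraries were not split between the comparisons, which would leave 1 library on each side, so part of the excess may come from sharing them. Opposite calls were made for 3 genes, Nmar_0010, Nmar_0585 and Nmar_1280, where independent lists would give 272. Nmar_1280 rose under limitation (log2 3.10, edgeR adjusted p = 0.000115) and fell under toxicity relative to the median gene (log2 -1.74, edgeR adjusted p = 0.00578), although its mean CPM was above replete in both groups. Nmar_0010 fell under limitation relative to the median gene (log2 -2.20, edgeR adjusted p = 0.0351), although its mean CPM was 71.6 in replete and 330.0 in limited libraries, and rose under toxicity (log2 3.37, edgeR adjusted p = 0.00232). The number of shared calls was 130 without limited replicate 3, 465 and 522 without replete replicates 1 and 3 and 534 without toxic replicate 2.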

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

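The tests of depth and of the copper treatment, and the mixture simulation, were chosen only after the result was seen.

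Reads outside any gene took a larger share of all reads in the file than the 39.3% of the highest replete library: 47.1% in limited replicate 1, 42.5% in limited replicate 3, and 43.1%, 42.4% and 42.6% in toxic replicates 1, 2 and 3. Reads that could belong to more than a single gene also exceeded the highest replete share of 0.837%, at 1.55% and 7.09% in limited replicates 1 and 3 and 3.73%, 2.08% and 1.27% in toxic replicates 1, 2 and 3. Neither kind of read entered the comparisons. All reads in the file include those that were not unique, and their share differed too. It was 32.7% and 23.0% in replete replicates 1 and 3, and 26.7% and 11.3% in limited replicates 1 and 3. In toxic replicates 1, 2 and 3 it was 14.5%, 21.3% and 22.2%. A lower share of non-unique reads raises the other shares, so the excess outside genes may come partly from this total.

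Counts in the limited and toxic libraries were spread over more genes than in the replete ones, also outside the S-layer gene, where 90% of the counts took 599 to 1125 genes against 241 and 266. Lower depth is argued against as the cause, since with every library thinned to 33897 counts the least even of these 5 libraries still needed 186 genes for 90% of its counts, against 6 and 8 in the replete ones, and 527 against 227 and 241 outside the S-layer gene at 10763 counts each. An even background of reads in a share that differs between libraries may account for much of it. Such reads could come, for example, from DNA left after the removal step. Of the 1057 genes called in limited against replete, 93.0% moved the same way from toxic replicate 3 to toxic replicate 1, which share a treatment. Simulated background without any changed gene gave 1025 and 1054 calls. Its profile and shares were taken from these same libraries, so many calls were built in. The simulation therefore cannot tell background from treatment. The copper treatment itself stays open, because the S-layer gene's share ranged over 57.1 percentage points within the limited and 32.2 within the toxic group, against 42.1 and 37.0 between the replete mean and theirs, yet none of the 5 libraries reached the replete share. In the mixture fit with limited replicate 3 as source, the fitted background was 52.9%, 23.2% and 7.67% of the count total in toxic replicates 1, 2 and 3. Background and replete profile were fitted separately and need not add up to the counts. Background alone would lower the scale of the replete profile below the 100.3% and 99.5% of replete replicates 1 and 3. In the toxic libraries it was 106.3%, 119.1% and 143.1%, which argues against background as the only cause there. Limited replicate 1 stood lower, at 60.9%, and is not covered. The anchor genes that set this scale leave out Nmar_1547. A lower Nmar_1547 share raises the share of other genes, so the scale is not evidence separate from that share. The shares of treatment and background cannot be told apart here, as both separate the replete libraries from the other 5.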

How the results depend on the processing

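The causes of the differences below were not tested. Of 81 results for named genes, 67 kept their direction and side of the threshold under DESeq2, 79 under RLE, 67 under the replicate block and 31 under library totals, where 30 turned. Of the named genes' calls 64 were lost with a library left out, 19 of them without limited replicate 3 and 14 without replete replicate 1, with log2 changes at 70.7% to 160.3% of those reported (median 97.0%). Calls under DESeq2 numbered 853, 623 and 109 for limited against replete, toxic against replete and toxic against limited, and under limma-voom 1063, 774 and 162. The thinning, the mixture, the removal of Nmar_1547 and the joint removal of libraries were chosen after the data were seen. The planned removal of non-coding features gave no value, as no entry could be identified as such here.

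Against library totals the calls were 1492 for toxic against replete, 10 for toxic against limited and 1397 shared, and camera called 5 lists in toxic against limited. The stricter filter, which tests fewer genes, gave 428 (limited) and 327 (toxic against replete), of which 289 and 207 were among the reported calls. Fitting only the groups compared left 24 in toxic against limited. An adjusted p under 0.01 left 571 and 41 for the toxic comparisons. Deviations of same-numbered libraries from their group means correlated at 0.043 between replete and limited and at -0.21 and -0.22 between limited and toxic. In groups of 2 the deviations of the libraries mirror each other, so these values cannot tell whether replicate numbers pair the libraries. With the replicate block 531 genes were called in toxic against replete, 75 in toxic against limited and 489 were shared. The mixture with limited replicate 3 as source gave 4, 96 and 17 calls (2, 9 and 10 of them reported ones in the same direction), and with toxic replicate 1 as source 46, 43 and 200 (38, 6 and 112). Thinning gave 100, 1 and 44 (86, 1 and 43). Without Nmar_1547 and against totals limited against replete had 1301 calls (1246 rose), toxic against replete 1257 (1241 rose) and toxic against limited 32. With neither limited replicate 3 nor toxic replicate 1, 384 (limited against replete) and 31 (toxic against limited) were called. With an estimated correlation camera called 0, 0 and 0 lists in place of 5, 5 and 3, and fry called 3 in toxic against replete and 0 in toxic against limited.

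Leaving out each library in turn gave 158 to 1168 calls in limited against replete, 505 to 1115 in toxic against replete, 3 to 292 in toxic against limited and 130 to 1003 shared. The lists called by camera numbered 5 to 5, 5 to 5 and 1 to 5. Signs that turned for limited against replete under library totals were Nmar_1259 1.09, Nmar_1663 1.45, Nmar_0277 1.52, Nmar_0284 2.52, Nmar_0279 2.49, Nmar_0183 1.49, Nmar_1543 1.49, Nmar_1110 0.28, Nmar_0954 1.01, Nmar_1088 1.82 and Nmar_1262 2.21. For toxic against replete they were Nmar_1500 0.53, Nmar_1501 0.53, Nmar_1502 0.26, Nmar_1503 0.31, Nmar_0588 0.22, Nmar_1259 1.59, Nmar_1354 2.52, Nmar_1663 2.07, Nmar_0277 1.18, Nmar_0284 1.91, Nmar_0286 1.94, Nmar_0183 1.66, Nmar_0185 0.44, Nmar_0184 1.35, Nmar_1110 1.23, Nmar_0954 1.61, Nmar_0061 0.048, Nmar_0700 0.26 and Nmar_0029 2.33. Nmar_1136 turned to -0.0071 with DESeq2, -0.0052 with RLE and, with each library left out, ranged from -0.26 (without replete replicate 3) to 0.43. In toxic against limited Nmar_1698 turned to -0.56 without limited replicate 3 and ranged from -0.59 (without toxic replicate 3) to 3.40, and Nmar_1503 from -0.042 (without toxic replicate 3) to 4.45. Camera's direction turned for ammonia monooxygenase without limited replicate 3 (adjusted p = 0.972, from 0.00109 up over single libraries left out) and for hydroxyectoine synthesis without toxic replicate 3 (adjusted p = 0.990, from 0.353 up). Under the mixture with limited replicate 3 as source 13 of 26, 12 of 26 and 6 of 25 named genes changed sign (limited against replete, toxic against replete and toxic against limited), and with toxic replicate 1 as source 9, 13 and 7 did, counted together and not gene by gene. With 33897 counts, limited replicate 1 cannot show changes of genes below its floor of 88.5 CPM.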

Other observations

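The mixture model, the ratios to amoA and the test of CPM ratios between toxic libraries were chosen only after the results were seen.

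Ratios within a library do not depend on its scaling, although background reads can still move them. Per 100 counts of amoA, Nmar_1500, the amoX gene Nmar_1501 held 20.2 ± 2.95 counts in replete (SD, n = 2), 19.3 ± 4.56 in limited (n = 2) and 19.8 ± 2.74 in toxic libraries (n = 3). The amoB gene Nmar_1503 held 40.3 ± 1.98, 40.4 ± 4.89 and 34.3 ± 4.52. The nirK gene Nmar_1667 held 65.6 ± 4.00 in replete, 28.5 ± 8.55 in limited and 44.3 ± 5.84 in toxic libraries, lower than both replete values in all 5. The ammonium transporter gene Nmar_1698 held 92.2 ± 2.51, 75.2 ± 6.42 and 37.5 ± 3.19, and the S-layer gene Nmar_1547 held 3906 ± 397, 2424 ± 556 and 1451 ± 344. The multicopper oxidase gene Nmar_1354 held 10.3 ± 0.793 in replete and 41.5 ± 5.25 in toxic libraries, with 6.09 and 35.8 in limited replicates 1 and 3. With 2 replete and 3 toxic libraries there are 10 splits, so an exact permutation test could not go below p = 0.1 and none is reported.

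Against the mixture of replete profile and even background, with limited replicate 3 as the source, edgeR found 96 genes that departed in toxic libraries, 88 upwards and 8 downwards. With toxic replicate 1 as the source it found 43 upwards, of which 35 were shared, and 0 downwards. Nmar_1354 departed by log2 2.01 (SE 0.22, edgeR adjusted p = 0.000225) and by 1.35 under the other source (edgeR adjusted p = 0.0469). The carbon fixation gene Nmar_1308 departed by 1.22 (edgeR adjusted p = 0.00627) and by 0.55 under the other source, without passing (edgeR adjusted p = 0.640). With limited replicate 3 as source the ammonium transporter gene Nmar_1698 departed by -1.08 (edgeR adjusted p = 0.00454) and Nmar_1547 by -1.20 (edgeR adjusted p = 0.00288). Under the other source Nmar_1698 and Nmar_1547 departed by -1.01 and -1.0 without passing (edgeR adjusted p = 0.194 and 0.617). Complex I, lower relative to the median gene in the report, had 0 of 10 genes departing under either source in edgeR, with medians of -0.067 and -0.095. Other lists reported as lower had positive medians against the mixture in toxic libraries, at 0.30 and 0.32 for complexes III and IV (1 and 1 genes upwards in edgeR), 0.27 and 0.29 for carbon fixation (2 and 1 upwards), 0.47 and 0.57 for cell division (1 and 0 upwards) and 0.10 and 0.15 for ammonia monooxygenase. In limited libraries the 2 sources gave medians of 0.47 and 0.10 for complex I, 0.48 and -0.085 for complexes III and IV, -0.34 and -0.15 for carbon fixation, -0.11 and -0.089 for cell division, 0.76 and 0.33 for ammonia monooxygenase and -3.11 and -0.083 for hydroxyectoine synthesis. There edgeR found 10 genes upwards and 36 downwards with toxic replicate 1 as the source. With limited replicate 3 as the source, limited replicate 1 was left by itself and assumed to vary like the other groups, and 4 of those 10 were found upwards: Nmar_1273, Nmar_1280, Nmar_1708 and Nmar_1766, the last 2 named after their values were seen. Nmar_1273 and Nmar_1280 had been picked for their fall from limited to toxic libraries, so their departure from a background taken from a toxic library repeats that choice, and the cause of their high level was not tested.

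The 88 genes above the mixture in toxic libraries included Nmar_0010 (log2 4.92, edgeR adjusted p = 0.000105) and Nmar_0011 (log2 3.91, edgeR adjusted p = 0.000669). Nmar_0010 had been picked for its rise from limited to toxic libraries, so its departure from a background taken from limited replicate 3 partly repeats that choice, and with toxic replicate 1 as the source it was 2.38 (edgeR adjusted p = 0.000132). Background may still account for some of them, and the test left it open: their median ratio of CPM in toxic replicate 3 to toxic replicate 1 was 0.704 (quartiles 0.576 and 0.896), between the 0.156 of genes of low replete level and an equal level. They held 16 pairs of consecutive locus tags in 12 runs, against a mean of 4.29 and a highest of 14 among 10000 random sets (one-sided permutation p = 0.0001, the smallest these draws can give). Neighbouring genes may rise together, a hypothesis that needs the genome's operon map, not used here. The random sets were drawn from all tested genes and not matched on expression, so neighbouring genes of similar level could give the same excess.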
